A study of Homo sapiens with 6 samples.

How the data were processed

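Poly(A)-selected RNA of HEK293T cells was measured in 3 wild-type and 3 SMARCA3 knockout libraries, made with a stranded mRNA kit and sequenced as paired reads, per the labels' protocols. The authors deposited a table of raw counts, whole-number read counts per gene symbol with 1 column per library, not normalized and not pooled. Trim Galore, STAR 2.4, Picard, HTSeq 0.9.1 and DESeq2 are named with the hg38 build, per the submitters' processing notes, which give these tools no role or order. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of a gene and of a gene overlapping it on the other strand may not have been told apart. Of the 130 named genes, 51 have exons that overlap another annotated gene and 44 overlap one on the other strand.

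Columns were assigned to samples by the column names given in the labels. The table had 56832 symbols, of which 36119 had a count in some library, and 0 rows that named no gene. Total counts ran from 33125811 to 41593655 per library. A floor of 3 counts corresponds to 0.0721 to 0.0906 CPM in a library, taken here over its unscaled total counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 3.30 to 13.6 over pairs), so all 6 libraries were counted separately.

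Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 18061, libraries were scaled by TMM (factors 0.997 to 1.005), and the quasi-likelihood F test of knockout against wild-type was fitted with robust = FALSE and no covariate. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The common biological coefficient of variation was 6.12%. CPM values are counts per 1000000 TMM-scaled counts of the tested genes in the library, given as the mean and SD of 3 libraries. The log2 fold change and its SE come from the edgeR fit. For HLTF and SHPRH an exact permutation test of log2 CPM was added, whose smallest two-sided p is 0.1.

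The 35 gene lists were tested with camera in limma 3.58.1 on TMM-scaled log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 34 lists with at least 5 tested members. The correlation estimated for each list and the fry rotation test, which asks whether a list moves on its own and does not compare it with other genes, were alternatives. Lists, the edgeR and camera tests, the rule for named genes and all alternatives but the 3 named below as added were fixed before the data were examined. The rule named HLTF and SHPRH, then the 10 largest positive and 10 largest negative log2 fold changes among called genes with at least 5 CPM in the higher group, non-overlapping CPM ranges and an approved symbol that is not a pseudogene, then up to 2 called members per direction and list with the smallest p. A gene named by more than 1 part counts under each, and 1 gene that the rule names is not reported here.

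Gene positions, types, lengths and GC content were taken from the GENCODE annotation of the same build, matched by symbol or by a former symbol. This matched 30404 of the 56832 symbols, 80.1% of the tested genes and 89.6% of the called genes. Neighbour medians used the 40 nearest positioned genes with a mean of at least 2 CPM, 20 on each side, and blocks held about 40 such genes. The way chromosomes were divided into blocks was changed after results were seen, since it had left blocks of 1 gene at chromosome ends. The coordinates are those of the annotation, 1-based.

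Alternatives were RLE size factors, library size only, no filter on low counts, at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block, each library left out in turn, an adjusted p threshold of 0.01 and glmTreat against a log2 fold change of 1. Removal of the neighbour median, removal of a loess trend on GC content and length, and thinning to the smallest total were added after seeing the data. The procedure was tested on simulated data drawn from the means and totals of these libraries, with 17760 genes tested. Of 50 genes changed at each size, the test recovered 36% at the smallest size simulated, which was below 1.5-fold, 82% at 1.5-fold, 84% at 2-fold and 98% at 4-fold, and of its 170 calls 150 were of these genes, 12 of the 30 genes shifted to test a list and 8 of unchanged genes. The data gave 5737 calls, so far fewer genes changed in the simulation and its adjustment of p was stricter. Its recovery rates therefore do not carry over to the comparison made here.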

Results

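Poly(A)-selected RNA was sequenced from HEK293T, an adherent human embryonic kidney line that carries adenovirus DNA and expresses the SV40 large T antigen. The 6 libraries formed 2 groups, 3 from wild-type cells and 3 from cells labelled as knocked out for SMARCA3, the protein encoded by HLTF. The series concerns SMARCA3 as a ubiquitin ligase for histone H3 and its link to H3K9 trimethylation, a mark of silenced chromatin, and the comparison here asks which mRNAs differ between cells labelled as knocked out for it and wild-type cells. Total counts were 41593655, 38825312 and 38199454 in wild-type replicates 1 to 3 and 34395448, 36804337 and 33125811 in knockout replicates 1 to 3, so each knockout library was shallower than each wild-type library. Across genes, log2 CPM correlated at r = 0.994 to 0.996 between libraries of a group and at r = 0.978 to 0.983 between libraries of different groups. The labels do not say whether the replicates were separate cultures or clones, so the p-values measure only the spread between these samples, which may be technical.

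HLTF mRNA, which encodes the targeted SNF2-family helicase and RING ubiquitin ligase, was lower in the knockout but present in all 6 libraries. It measured 215, 191 and 195 CPM in wild-type replicates 1 to 3 and 141, 140 and 149 CPM in knockout replicates 1 to 3. The means were 200.3 ± 13.1 CPM in wild-type and 143 ± 5.26 CPM in the knockout (SD, n = 3 per group), a log2 fold change of -0.48 (SE 0.05, edgeR adjusted p = 4.65e-05). The ranges did not overlap, and the exact permutation test gave p = 0.1, the smallest two-sided p that 3 against 3 libraries allow. HLTF lies on chromosome 3 between 149030127 and 149086554 on the minus strand (hg38). Its 40 nearest expressed genes had a median log2 fold change of -0.50, with 27 called lower and 4 called higher, and HLTF stood at percentile 52.5 among them. With that median removed, an alternative chosen after seeing the data, the log2 fold change of HLTF was 0.02 (adjusted p = 0.839, the highest of 17 alternatives, of which the lowest was 4.38e-19 with no filter on low counts). The 40 neighbours lie between 140941830 and 155944026, while the block of lowered genes that holds HLTF starts at 142449235. Some neighbours thus lie outside that block, whose median was -0.61, further from 0 than the value of HLTF. Counts per gene do not show whether the HLTF sequence or protein was altered.

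**Figure D1:**
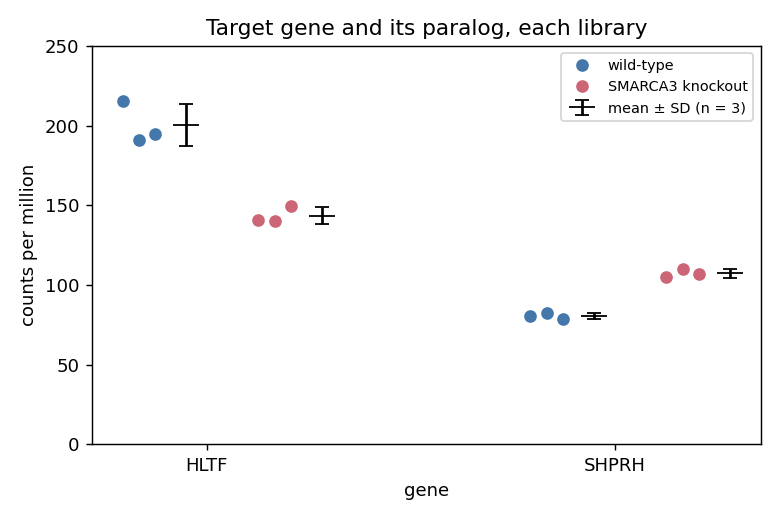
CPM of HLTF and SHPRH in each of the 6 libraries (points), with the mean ± SD of the 3 libraries of a group (bars). HLTF reads 191 to 215 CPM in wild-type and 140 to 149 CPM in the knockout, and SHPRH is higher in the 3 knockout libraries.

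SHPRH, the closest paralog of HLTF and like it a SNF2-family helicase with a RING domain, moved the other way. It rose from 80.4 ± 1.78 to 107 ± 2.83 CPM (SD, n = 3), a log2 fold change of 0.42 (SE 0.04, adjusted p = 3.63e-05), and its exact permutation p was again 0.1. SHPRH lies on chromosome 6 between 145864245 and 145964423, and its exons overlap AL356599.1 on the other strand by 1779 bases. The 40 expressed genes nearest to SHPRH had a median log2 fold change of 0.24. With that median removed, its log2 fold change was 0.18 (adjusted p = 0.0117, the highest of 17 alternatives, of which the lowest was 3.05e-11 with DESeq2).

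The 10 rises named next are the largest among called genes with at least 5 CPM in the higher group, non-overlapping CPM ranges and an approved symbol that is not a pseudogene. C15orf60 (current symbol REC114, a meiotic recombination protein) went from 0.0844 ± 0.0537 to 41.2 ± 1.89 CPM (SD, n = 3), a log2 fold change of 8.87. HAS2, the hyaluronan synthase of embryonic tissue, went from 1.30 ± 0.109 to 54.4 ± 2.54 CPM, a log2 fold change of 5.39. FLRT2, an adhesion protein of axon guidance, rose by 5.47 and the kelch protein gene KLHL4 by 7.34 on the log2 scale. The adhesion G protein-coupled receptor gene ADGRD1 (5.08), the microtubule regulator STMN2 (4.45), the intracellular FGF homologue FGF13 (4.40), the CD30 receptor gene TNFRSF8 (4.32), AFF2 (4.01) and SYTL5 (3.10) completed these 10, given as log2 fold changes. Their adjusted p-values lay between 3.63e-11 for HAS2 and 8.38e-08 for SYTL5 in edgeR.

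The 10 falls named by the same rule include structural and metabolic genes. NEFM, the medium neurofilament subunit, fell from 34.8 ± 2.85 to 0.0501 ± 0.0633 CPM (SD, n = 3), a log2 fold change of -9.40 that rests on 5 counts in the 3 knockout libraries. COL2A1, the fibrillar collagen of cartilage, fell from 25.7 ± 0.322 to 0.454 ± 0.0883 CPM, and OXCT1, which activates ketone bodies for oxidation, from 28.3 ± 1.09 to 0.637 ± 0.109 CPM. The actin crosslinker FLNC had a log2 fold change of -4.95, the mitochondrial fatty acid oxidation enzyme DECR1 -4.86, the surface protein CD109 -4.72 and the TRAIL decoy receptor TNFRSF10D -4.55. The epithelial splicing regulator ESRP2 (-4.43), the mesenchymal transcription factor PRRX1 (-4.28) and the small GTPase gene RASL10B (-4.27) followed. Of these 10 genes, PRRX1 had the highest adjusted p, 1.44e-07 in edgeR.

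**Figure D2:**
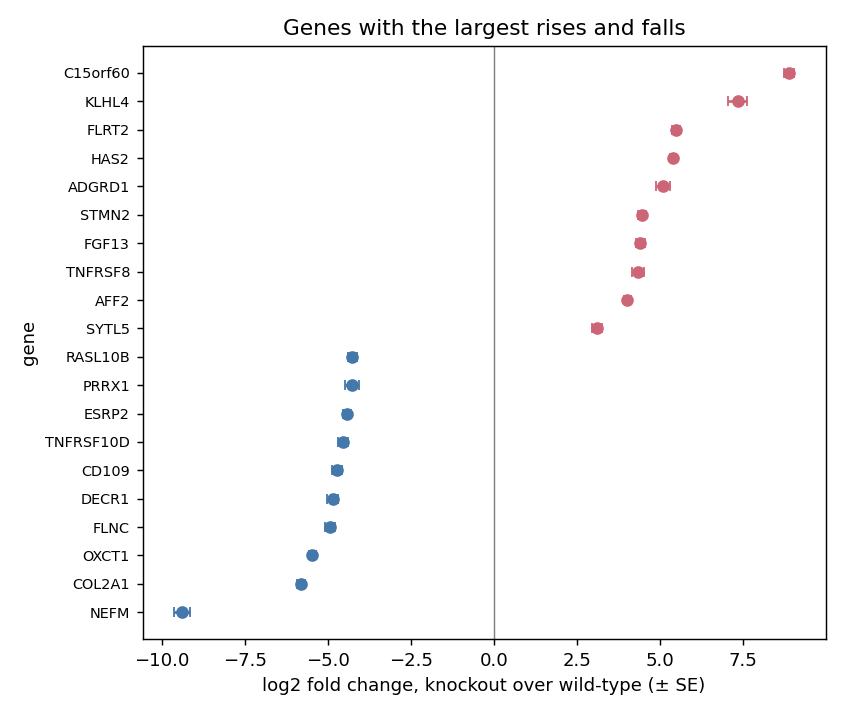
Log2 fold change of knockout over wild-type with its standard error for the 10 genes with the largest rises (red) and the 10 with the largest falls (blue) that met the rule for named genes. C15orf60 stands at 8.87 and NEFM at -9.40.

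Of 18061 genes tested with edgeR, 5737 had an adjusted p under 0.05, with 2532 higher and 3205 lower in the knockout. A log2 fold change of at least 1 in size was reached by 920 of them, 280 higher and 640 lower.

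Among 29 writers, readers and silencing complexes of H3K9 methylation, 5 were higher, 3 lower and 21 not called, with the same counts adjusted over the list alone. EHMT2 (G9a), which places mono- and dimethylation on H3K9, rose from 54.3 ± 5.74 to 69.6 ± 4.51 CPM (SD, n = 3), and MORC2, an ATPase that acts with the HUSH silencing complex, from 49.9 ± 0.899 to 59.0 ± 1.08 CPM. FAM208A (TASOR), a core subunit of HUSH, fell from 177 ± 14.8 to 110 ± 5.26 CPM, a log2 fold change of -0.69 (SE 0.06), and its exons overlap CCDC66 on the other strand. SUV39H2, a H3K9 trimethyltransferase, fell from 50.4 ± 1.33 to 33.4 ± 0.0467 CPM. SUV39H2 and MORC2 had log2 fold changes of -0.59 and 0.24 beside neighbour medians of -0.67 and 0.29. The list as a whole was not called (camera adjusted p = 0.360). Of 11 H3K9 demethylases, KDM7A (0.20) and KDM4A (0.17 on the log2 scale) rose, 0 fell and 9 were not called, again also when adjusted over the list alone (camera adjusted p = 0.226). Over the alternatives the adjusted p ran from 0.000352 to 0.0699 for KDM7A and from 0.0138 to 0.114 for KDM4A.

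SNF2-family ATPases, the chromatin remodelling and translocase family to which HLTF belongs, leaned upward. The list leaves out HLTF itself, which was called lower (log2 fold change -0.48). Of the 30 members tested, 11 rose, 0 fell and 19 were not called, also when adjusted over the list alone, and the median log2 fold change was 0.08 (camera adjusted p = 0.0168, adjusted p = 0.533 with an estimated correlation). SHPRH was among them, and CHD2 rose from 114 ± 1.68 to 147 ± 4.99 CPM (SD, n = 3). Of 28 histone ubiquitin ligases and deubiquitinases, a list that again leaves out HLTF, 7 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.599). USP44, a deubiquitinase of histone H2B, had a log2 fold change of -0.96 and the Polycomb subunit BMI1 of -0.57, the latter beside a neighbour median of -0.53 on chromosome 10. Of 29 genes of DNA damage tolerance and fork protection, a list that also leaves out HLTF, 6 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.364). The replication fork protein gene CXorf57 (RADX) rose by 0.40 on the log2 scale. UBE2N, the E2 enzyme that builds K63-linked chains with HLTF and SHPRH, had a log2 fold change of -0.25 and the helicase FBXO18 (FBH1) of -0.66, beside neighbour medians of -0.13 and -0.60. Exons of UBE2N overlap NUDT4 on the other strand by 2457 bases.

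Zinc finger genes with ZNF names, many of which encode KRAB repressors that recruit H3K9 methylation, leaned higher as a group. Of 447 tested, 135 were higher, 38 lower and 274 not called, with 142 higher and 40 lower adjusted over the list alone, and the median log2 fold change was 0.13 (camera adjusted p = 5.12e-05, adjusted p = 0.259 with an estimated correlation). ZNF813 rose from 0.508 ± 0.0717 to 3.11 ± 0.247 CPM (SD, n = 3) and ZNF556 by 4.16 on the log2 scale (SE 0.24), both on chromosome 19. ZNF804A had a log2 fold change of -4.03 and ZNF532 of -1.27. On chromosome 19 the median was 0.19 over 206 ZNF genes and on other chromosomes 0.09 over 239. With the neighbour median of each gene removed the list was not called (adjusted p = 0.0737, within a range of 5.32e-06 to 0.259 over its alternatives). ZNF genes are often neighbours of each other, as on chromosome 19 from 52 Mb on, with 67 ZNF genes and 46 others. The removal therefore also takes away a rise shared by the family, and it cannot show that position accounts for the list.

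Gene families kept silent in most somatic cells showed no common rise among the members with enough counts to test. These were 8 of 56 clustered protocadherins, 14 of 116 cancer-testis and germline genes and 5 of 400 olfactory receptors. The other members were not tested. Of 8 clustered protocadherins tested, 4 fell, 0 rose and 4 were not called, with 5 lower adjusted over the list alone, and the median log2 fold change was -0.62 (camera adjusted p = 0.0416, adjusted p = 0.301 with an estimated correlation). PCDHGC3 fell from 3.39 ± 0.131 to 1.95 ± 0.137 CPM (SD, n = 3) and PCDHA10 from 0.388 ± 0.0894 to 0.155 ± 0.0793 CPM, and both are uncertain because members of these clusters share exons. Of 14 cancer-testis and germline genes, 2 were higher and 5 lower, with 3 higher and 5 lower adjusted over the list alone, and the median of -0.12 was unchanged with MAGEA6 at its bound (camera adjusted p = 0.354). MAGEA6 went from 128 counts to 0, at least 37.5-fold lower against a floor of 3 counts over the group, and MAGEA3 from 76 counts to 1, a ratio of 66.7 with a 95% counting interval of 11.6 to 2671. These are near-identical copies whose reads can be confused. STK31 and TEX14 were higher by 1.17 and 0.37 on the log2 scale, with adjusted p-values of up to 0.145 and 0.192 over the alternatives. Of 5 olfactory receptors tested, OR51B5 rose by 4.83 and OR11H7 had a log2 fold change of -1.35, and adjusting over the list alone gave the same counts (camera adjusted p = 0.783).

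Among 36 HOX genes, which set position along the body axis, 5 rose and 12 fell, also when adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.0775). HOXC12 and HOXC13 rose by 0.95 and 0.37 on the log2 scale, and HOXB9 had a log2 fold change of -0.28. Of 24 imprinted genes, 6 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.111). The mannose-6-phosphate receptor gene IGF2R rose from 194 ± 5.66 to 271 ± 7.37 CPM (SD, n = 3), beside a neighbour median of 0.29, and the adaptor gene GRB10 by 0.31. PPP1R9A had a log2 fold change of -1.35 and MKRN3 of -2.39.

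Cholesterol synthesis genes fell together. Of 23 enzymes and regulators tested, 18 were lower, 0 higher and 5 not called, with 19 lower adjusted over the list alone, and the median log2 fold change was -0.38 (camera adjusted p = 4.18e-08, adjusted p = 0.232 with an estimated correlation). IDI1, which isomerises isopentenyl diphosphate, fell from 151 ± 5.04 to 67.4 ± 2.09 CPM (SD, n = 3), a log2 fold change of -1.16 beside a neighbour median of -0.59 on chromosome 10. FDFT1, the squalene synthase on chromosome 8, fell from 193 ± 2.08 to 128 ± 1.11 CPM beside a neighbour median of -0.07.

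Hypoxia and glycolysis genes also leaned lower, with 12 of 24 lower, 4 higher and 8 not called, 14 lower and 4 higher adjusted over the list alone and a median of -0.19 (camera adjusted p = 0.0416, adjusted p = 0.259 with an estimated correlation). The neuronal enolase ENO2 fell from 22.5 ± 1.14 to 7.03 ± 0.680 CPM (SD, n = 3) and the vasodilator peptide gene ADM from 3.88 ± 0.321 to 0.677 ± 0.230 CPM, while hexokinase HK2 and the MYC antagonist MXI1 each rose by 0.19 on the log2 scale, MXI1 beside a neighbour median of 0.12.

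Of 78 nuclear-encoded respiratory chain genes, 24 were lower and 3 higher, with 24 and 4 adjusted over the list alone (camera adjusted p = 0.111). The complex I genes NDUFA6 and NDUFA10 had log2 fold changes of 0.38 and -0.38 beside neighbour medians of 0.34 and -0.31, and the ATP synthase genes ATP5H (ATP5PD) and ATP5C1 (ATP5F1C) of 0.19 and -0.71 beside 0.16 and -0.61. None of these 4 genes was called once the neighbour median was removed (adjusted p of 0.224 for ATP5C1 to 0.616 for NDUFA6).

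Of 27 ATF4 and amino acid response genes, 8 were higher and 4 lower, with 10 and 4 adjusted over the list alone (camera adjusted p = 0.175). The stress protein gene NUPR1 rose from 1.51 ± 0.0861 to 7.80 ± 0.948 CPM (SD, n = 3) and the serine synthesis enzyme PHGDH by 0.27 on the log2 scale, whereas ALDH1L2 and TRIB3 had log2 fold changes of -0.50 and -0.48. Of 19 endoplasmic reticulum chaperones, 9 were lower and 2 higher, also when adjusted over the list alone (camera adjusted p = 0.111). The lectin chaperone CALR and the Hsp70 of the same compartment, HSPA5, had log2 fold changes of -0.34 and -0.26, while CRELD2 rose by 0.35 beside a neighbour median of 0.47 and SEL1L by 0.14. Of 18 heat shock proteins, 8 fell, 1 rose and 9 were not called, with 9 lower and 1 higher adjusted over the list alone and a median of -0.11 (camera adjusted p = 0.0416, adjusted p = 0.532 with an estimated correlation). HSPA4L fell from 125 ± 5.82 to 69.8 ± 2.29 CPM (SD, n = 3) and FKBP4 by 0.25 on the log2 scale, and HSPA1B, which shares nearly all its sequence with HSPA1A and is uncertain, was higher by 0.42, a call lost in 3 of 17 alternatives (adjusted p of 5.13e-13 to 0.119).

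Interferon-stimulated genes leaned lower, with 11 of 24 lower, 2 higher and 11 not called, and 11 lower and 3 higher adjusted over the list alone. The median was -0.20, also with DTX3L at its bound (camera adjusted p = 0.0168, adjusted p = 0.259 with an estimated correlation), and -0.11 over the 7 members with at least 5 CPM. With at least 1 CPM required in 3 libraries the list was not called (adjusted p = 0.0653, within 0.00495 to 0.259 over its camera alternatives, while fry, which does not compare it with other genes, gave 0.000219). IFIT5, a sensor of viral RNA ends, fell from 12.9 ± 1.13 to 3.55 ± 0.351 CPM (SD, n = 3) and USP18, which removes ISG15, from 16.7 ± 0.556 to 6.85 ± 0.0927 CPM, while IFITM3 and STAT2 were higher by 0.60 and 0.19 on the log2 scale.

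Of 25 p53 target genes, 10 fell, 3 rose and 12 were not called, also when adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.0416, adjusted p = 0.259 with an estimated correlation). DDB2, a DNA damage sensor, and SPATA18, a mitochondrial quality protein, had log2 fold changes of -0.69 and -1.22, and EDA2R and SESN2 of 1.03 and 0.22.

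Of 33 G2 and mitosis genes, 12 were lower, 3 higher and 18 not called, with 14 lower and 4 higher adjusted over the list alone and a median of -0.11 (camera adjusted p = 0.0416, adjusted p = 0.546 with an estimated correlation). The mitotic cyclins CCNB1 and CCNB2 had log2 fold changes of -0.38 and -0.31, and topoisomerase TOP2A and the kinesin KIF2C rose by 0.34 and 0.15. Of 37 S-phase and E2F target genes, 4 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.718). The replicative helicase gene MCM5 rose by 0.56 beside a neighbour median of 0.32 and POLE by 0.28 beside 0.13, whereas MCM10 had a log2 fold change of -0.49 beside a neighbour median of -0.65 and CHAF1B of -0.20. Of 31 replication-dependent histone genes, 1 was higher and 3 lower, with 1 and 1 adjusted over the list alone (camera adjusted p = 0.920), and poly(A) selection takes up few of their mRNAs. HIST1H2BH rose by 1.41, and HIST1H1C and HIST1H2AC had log2 fold changes of -0.53 and -0.46.

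Immediate early genes moved in both directions, 3 of 28 higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.920). The stress factor ATF3 and MYC rose by 0.30 and 0.22 on the log2 scale, the phosphatase gene DUSP2 fell from 1.86 ± 0.342 to 0.145 ± 0.0786 CPM (SD, n = 3), and CYR61 (CCN1) had a log2 fold change of -0.48. Of 14 Wnt target genes, 5 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.783). The cyclin CCND1 and the feedback inhibitor AXIN2 rose by 0.43 and 0.56, and RNF43 and LGR5, which act at the Wnt receptor, had log2 fold changes of -0.80 and -0.61.

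Epithelial junction and keratin genes leaned lower. Of 18 tested, 10 were lower, 2 higher and 6 not called, with 10 and 3 adjusted over the list alone, and the median log2 fold change was -0.61 (camera adjusted p = 0.00735, adjusted p = 0.259 with an estimated correlation). Besides ESRP2, the keratin KRT18 fell from 30.7 ± 2.62 to 13.8 ± 0.539 CPM (SD, n = 3), while the desmosome genes DSP and JUP each rose by 0.29 on the log2 scale, beside neighbour medians of 0.12 and 0.20. Keratinocyte and squamous markers went the same way, with 3 of 5 lower and 0 higher, also when adjusted over the list alone, and a median of -0.36 (camera adjusted p = 0.0178, adjusted p = 0.259 with an estimated correlation). The laminin chain LAMA3 and the desmocollin DSC3 had log2 fold changes of -1.46 and -0.50.

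Extracellular matrix and mesenchymal genes split, 8 of 36 higher and 10 lower, also when adjusted over the list alone (camera adjusted p = 0.759). The matricellular protein gene SPARC rose from 2.04 ± 0.199 to 15.3 ± 0.687 CPM (SD, n = 3) and the transcription factor SNAI2 by 1.28 on the log2 scale (SE 0.07). COL4A1 of basement membranes had a log2 fold change of -0.79 and vimentin (VIM) of -0.64, the latter beside a neighbour median of -0.64 on chromosome 10. Neuronal genes split too, 5 of 24 higher and 6 lower, with 6 and 7 adjusted over the list alone (camera adjusted p = 0.959). STMN2 and the adhesion molecule NCAM1 (0.52) rose, and NEFM and CNTNAP2 (-1.32) fell. Of 15 kidney lineage genes, 2 were higher and 7 lower, with 3 and 7 adjusted over the list alone (camera adjusted p = 0.0775). The nephric regulator PAX2 rose from 4.52 ± 0.666 to 10.8 ± 0.0636 CPM (SD, n = 3) and SALL1 by 0.24 on the log2 scale, while EYA1 and the podocyte sialomucin gene PODXL had log2 fold changes of -1.87 and -0.77.

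Markers of other cell types gave no sign of a shared rise among the members with enough counts to test. Of 7 fibroblast markers, FBLN1 rose by 0.68 beside a neighbour median of 0.43, PRRX1 fell and 5 were not called (camera adjusted p = 0.783), and of 5 blood cell markers, CD34 rose by 0.94 (adjusted p of 0.00413 to 0.0765 over its alternatives, the highest with DESeq2, which did not call it), LCP1 had a log2 fold change of -0.74 and 3 were not called (camera adjusted p = 0.783). Adjusted over the list alone these were 1 higher and 1 lower for fibroblasts and 1 higher and 2 lower for blood cells. The 15 hepatocyte markers in the table had 0 members with enough counts to test.

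Ribosomal protein genes leaned higher, with 28 of 82 higher, 5 lower and 49 not called, 30 higher and 5 lower adjusted over the list alone, and a median log2 fold change of 0.10 (camera adjusted p = 0.000721, adjusted p = 0.657 with an estimated correlation). The fry test did not call the list (adjusted p = 0.0837, within 2.52e-06 to 0.657 over its alternatives). RPS12 rose from 976 ± 35.2 to 1415 ± 74.2 CPM (SD, n = 3) and RPL14 from 942 ± 25.8 to 1208 ± 15.7 CPM, a log2 fold change of 0.36 beside a neighbour median of 0.22, and RPL39L and RPL23A had log2 fold changes of -0.61 and -0.26, RPL23A beside a neighbour median of -0.23. Many of these genes have processed pseudogenes that can take their reads. In the list named nuclear-retained RNAs, 6 of 9 were higher, 1 lower and 2 not called, also when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.0348, adjusted p = 0.432 with an estimated correlation). Where its members lie in the cell was not measured here. The paraspeckle RNA NEAT1 rose by 0.42 and GAS5 by 0.35, and PVT1 had a log2 fold change of -0.33 whose call was lost in 13 of 17 alternatives (adjusted p of 0.0256 to 0.180). The share of counts from the mitochondrial genome was 3.69 ± 0.322% in wild-type and 3.66 ± 0.258% in the knockout. Of the 13 mitochondrially encoded genes 1 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.783), with MT-ND1 at 0.30, MT-CYB at -0.44 and MT-ND3 at -0.40.

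In all, camera called 13 of the 34 lists it could test, 4 higher and 9 lower, with a preset correlation of 0.01. With the correlation estimated for each list, 0 were called (lowest adjusted p = 0.232, 5 at an unadjusted p under 0.05), and fry called 22 in a direction and 34 for change in either direction. The median, mean and test of a list differed in sign for olfactory receptors, replication-dependent histones, extracellular matrix, immediate early, Wnt target, neuronal and fibroblast genes, none of which was called by camera.

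Cholesterol synthesis, epithelial junction and keratinocyte genes were called in each alternative except the estimated correlation. Leaving out a library ended the call of 7 lists, with the highest adjusted p at 0.0681 for SNF2-family ATPases and for hypoxia and glycolysis, both without wild-type replicate 3, 0.0859 for p53 targets without the same library, 0.113 for protocadherins and 0.0564 for nuclear-retained RNAs without knockout replicate 1, 0.146 for heat shock proteins without knockout replicate 2 and 0.116 for G2 and mitosis genes without wild-type replicate 1. Among single genes named here, 15 lost their call without some library. The highest adjusted p was then 0.0699 for KDM7A, 0.0795 for HIST1H2AC and 0.114 for SEL1L without wild-type replicate 2, and 0.108 for PCDHA10, 0.0957 for STK31, 0.0617 for EDA2R, 0.0562 for IFITM3, 0.1001 for STAT2 and 0.0604 for JUP without knockout replicate 1. It was 0.114 for KDM4A, 0.115 for TEX14 and 0.102 for OR11H7 without knockout replicate 2, and 0.0838 for SESN2, 0.0648 for KIF2C and 0.175 for PVT1 without knockout replicate 3.

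Other tools, filters and scalings also ended calls of named genes. DESeq2 did not call KDM4A, PCDHA10, STK31, TEX14, OR11H7, EDA2R, IFITM3, STAT2, HIST1H2AC, SEL1L, HSPA1B, CD34 or PVT1. With the replicate number as a block, KDM7A, KDM4A, PCDHA10, TEX14, STAT2, KIF2C, HIST1H2AC, SEL1L, HSPA1B, JUP and PVT1 were not called, and with no filter on low counts KDM4A, TEX14, STAT2, KIF2C, SEL1L and PVT1 were not. Robust dispersion ended the call of HSPA1B, and RLE size factors, limma-voom and thinning that of PVT1. Among lists, G2 and mitosis genes and heat shock proteins also lost their call with RLE size factors, the replicate block, thinning and at least 1 CPM required in 3 libraries. The last of these ended the calls of hypoxia and glycolysis and of interferon-stimulated genes too, and left too few protocadherins to test that list. The replicate block and thinning ended the call of p53 targets, and thinning that of protocadherins.

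**Figure D3:**
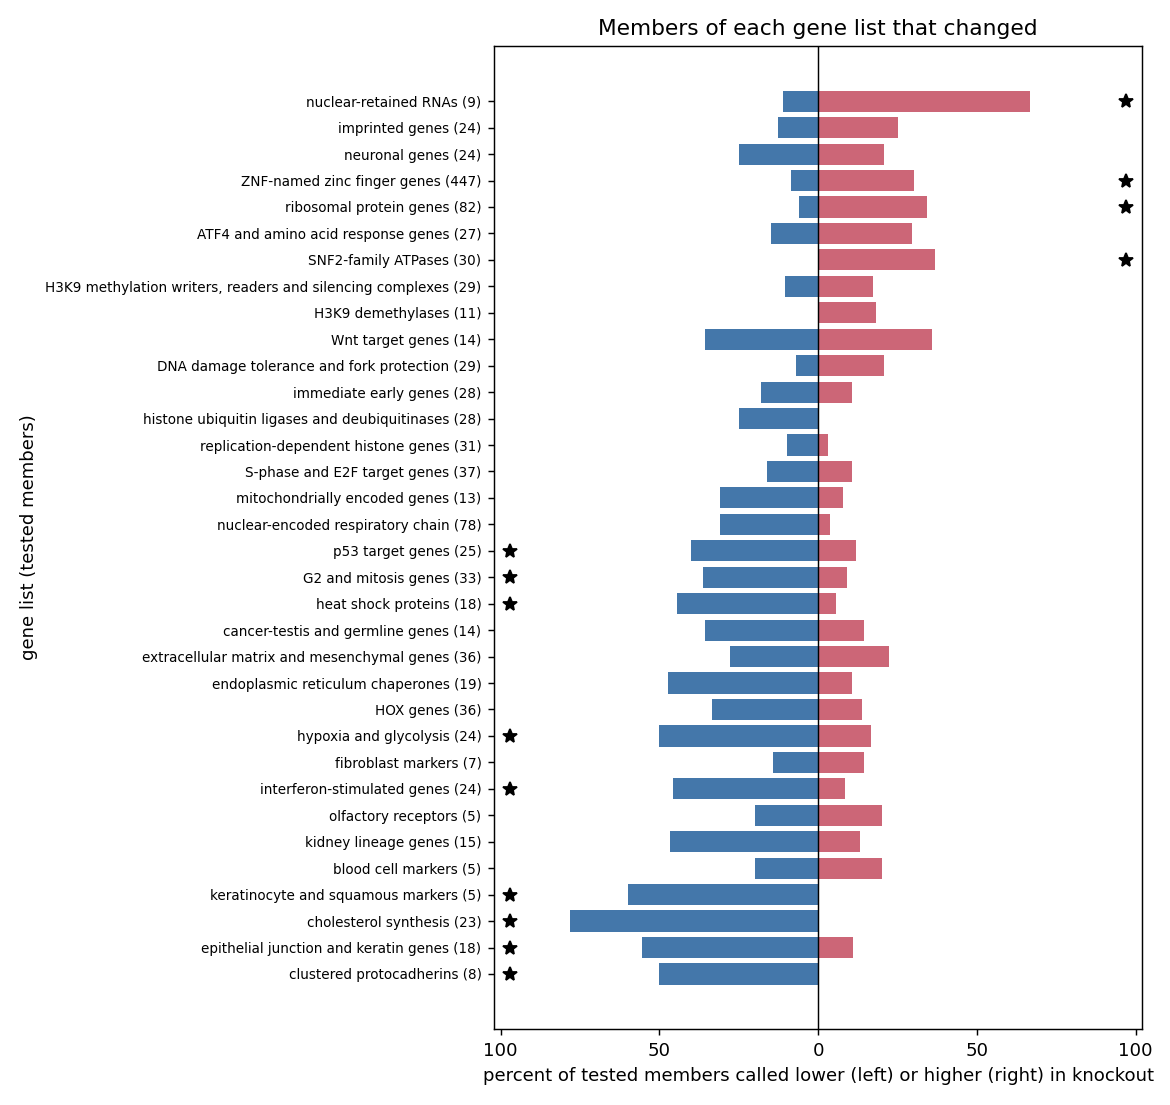
Percent of the tested members of each list called lower (blue, to the left) or higher (red, to the right) in the knockout, with the number tested in brackets and the lists ordered by median log2 fold change. Stars mark the 13 lists called by camera with the preset correlation, on the side of their direction.

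Neighbouring genes often moved together. Along the chromosomes, 26 of 294 blocks of about 40 expressed genes had a median log2 fold change beyond 0.2 in size, 16 higher and 10 lower, against at most 0 when the genes were shuffled 100 times. On chromosome 10, between 134465 and 27186924, 76 of 78 genes were called lower with a median of -0.61, and this stretch holds VIM, IDI1, BMI1, SUV39H2 and MCM10. On chromosome 3, between 142449235 and 179627647, 69 of 78 genes were called lower with a median of -0.60, and this stretch holds HLTF. On chromosome 22, between 26443423 and 50783663, 152 of 200 genes were called higher with a median of 0.35, MCM5 and MORC2 among them. On chromosome 6, between 142751467 and 170584692, 64 of 82 genes were called higher with a median of 0.27, SHPRH and IGF2R among them. Stretches of chromosome 17 went both ways, with medians of 0.29 from 39980797 to 48101521 and -0.23 from 21197280 to 35726409. Blocks beyond 0.2 held 8.79% of the genes placed in blocks, which have a mean of at least 2 CPM, and 16.8% of the called genes placed in blocks.

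With the neighbour median of each gene removed, HLTF and 17 other named genes were not called. For 13 of these 17 (MORC2, SUV39H2, BMI1, FBXO18, CRELD2, MXI1, NDUFA6, NDUFA10, ATP5H, ATP5C1, VIM, JUP and RPL23A) the log2 fold change was then between -0.13 and 0.08. The other 4 kept most of theirs and lost the call as the smaller value no longer passed the threshold: KDM7A went from 0.20 to 0.16, KDM4A from 0.17 to 0.14, KIF2C from 0.15 to 0.11 and TEX14 from 0.37 to 0.22 (SE 0.04 for KIF2C to 0.12 for TEX14, before and after). MCM10 was called in the other direction. The calls of 4 lists ended there too. The median went from 0.13 to 0.05 for ZNF genes and from -0.19 to -0.13 for hypoxia and glycolysis, but from -0.11 to -0.10 for G2 and mitosis genes and from 0.30 to 0.31 for nuclear-retained RNAs, so the neighbours did not take away the shift of the last 2 lists. For ZNF genes the neighbours include other ZNF genes, so the smaller median does not show that position accounts for their lean. With the GC and length trend removed, SESN2 (0.22 to 0.15), HIST1H2AC (-0.46 to -0.38), JUP (0.29 to 0.19) and PVT1 (-0.33 to -0.28) were not called. Nor were 4 lists that camera had called, with medians from -0.06 to -0.08 for p53 targets, -0.11 to -0.06 for G2 and mitosis genes, -0.11 to -0.09 for heat shock proteins and 0.30 to 0.25 for nuclear-retained RNAs. These lost calls do not show that the trend accounts for those genes and lists.

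**Figure D4:**
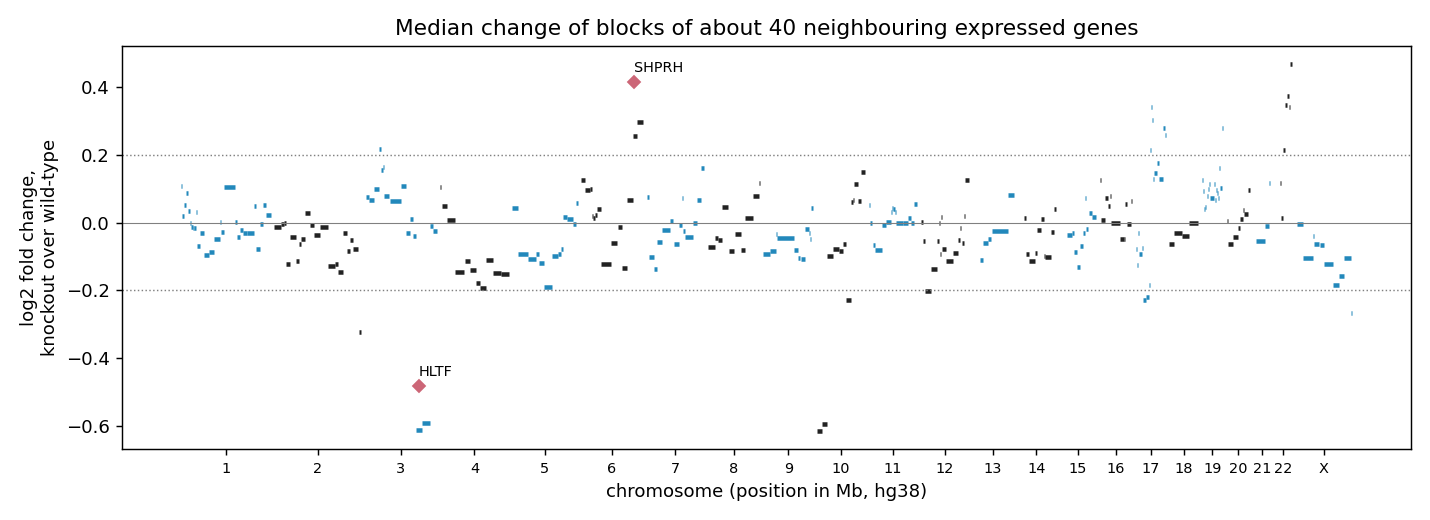
Median log2 fold change of knockout over wild-type for each block of about 40 neighbouring expressed genes, drawn over its span on chromosomes 1 to 22 and X, with dotted lines at 0.2 and -0.2 and diamonds for HLTF and SHPRH themselves. The lowest blocks, near -0.6, lie on chromosomes 3 and 10, and HLTF lies at the same place as the blocks of chromosome 3.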

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

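Removal of the neighbour median, removal of the GC and length trend, and thinning were chosen after seeing the data, while the other alternatives were planned. The count of changed genes ran from 4232 to 6213 over other scalings, filters, tools, the replicate block and left-out libraries, and with library size only or RLE scaling the share called higher stayed within 43.4% to 47.2%. A threshold of 0.01 left 3477 genes, 1421 higher and 2056 lower, by its construction. Genes with a log2 fold change of at least 1 numbered 524 (139 higher, 385 lower) with at least 1 CPM required in 3 libraries, where fewer genes were tested, and 377 (98 higher, 279 lower) with glmTreat. DESeq2 called 4541 genes and 77.7% of the edgeR calls were among them. Single genes were not scored with glmTreat or at the threshold of 0.01. Over the other alternatives HLTF kept its direction and call in all but the removed neighbour median. That one gave 0.017 (adjusted p = 0.839), because the median of its neighbours had shifted as far. For the same reason MORC2 (-0.050), SUV39H2 (0.071), MCM10 (0.16), CRELD2 (-0.13) and VIM (0.0029) changed sign there. Of the 129 other named genes 99 kept direction and call throughout the alternatives scored for single genes. Lists called by camera numbered 13, against 0 with estimated correlations, 22 with fry and 8 with at least 1 CPM in 3 libraries. Leaving out a library gave 7 to 13 lists, the lowest without wild-type replicate 3, and the cause was not tested. For extracellular matrix genes (median -0.12) camera pointed lower, while fry pointed the other way, to higher (fry adjusted p = 0.0136). Over all lists and alternatives, 55 list calls were lost and 15 gained, that of extracellular matrix genes with fry among them.

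The replicate block gave 4232 changed genes against 5737. Deviations of same-numbered libraries from their group means correlated at r = -0.226, -0.0144 and -0.0547. No library correlated best with the library of its own number, so these values gave no sign that the numbers pair the samples. Thinning all libraries to the smallest total gave 5537 changed genes.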

Other observations

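The tests of the GC and length trend, of copy number as the whole cause of the changes, of HLTF against its neighbourhood, of SHPRH with the neighbour median removed and of ZNF genes within chromosome 19, and the genes named in the next paragraph, were chosen only after the results were seen, as were the division into blocks and the requirement that ZNF genes outside chromosome 19 pass their bound by more than the standard error.

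Of the genes with at least 10 CPM in wild-type, 9 fell below 10% of that level in each knockout library, and 8 genes went from at least 1 CPM to under 0.05 CPM. Besides NEFM, COL2A1, OXCT1, ESRP2, FLNC and CD109, the first group held the glutathione transferase gene MGST1 (17.5 ± 0.579 to 1.48 ± 0.182 CPM, SD, n = 3), the protease inhibitor gene SPINT2 (12.9 ± 0.544 to 0.831 ± 0.127 CPM) and PRTFDC1 (19.8 ± 1.66 to 1.57 ± 0.328 CPM), the last beside a neighbour median of -0.51 on chromosome 10. The second group held the adhesion gene NCAM2, the small GTPase gene RAB32, NWD2, DTX3, the acyl-CoA synthetase gene ACSS3, the lysosomal galactosylceramidase gene GALC, MAGEA6 and UGT2B4. Of these, 0 lay in a block with a median below -0.2, and their neighbour medians ran from -0.19 for MAGEA6 to 0.25 for RAB32. DTX3L, a ubiquitin ligase, went from 109 counts to 0, at least 31.9-fold lower against a floor of 3 counts over the group, and its partner PARP9 went from 83 counts to 1, a ratio of 72.9 with a 95% counting interval of 12.7 to 2914. Genes gained on the same scale numbered 4, OR51B5 and 3 clone-named transcripts.

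The breadth of the difference between the groups was set against technical explanations. Only 10 splits of 6 libraries into 3 and 3 exist, and they cannot give a share under 0.05; the real split called 5737 genes and the highest other split 1. Thinning all libraries to the smallest total kept 92.8% of the calls in the same direction, and the 10 most abundant genes held shares of counts that differed by 0.298 percentage points between the groups, which argues against depth and against a few dominant genes. Of the called genes with a GC and length value, 83.7% were still called in the same direction with that trend removed, and of those with a neighbour median 68.7% with that median removed, which argues against either as the whole cause among these genes. Loss of SMARCA3 stays open as the cause, as does any other difference between the wild-type and knockout cells, such as descent from separate clones, which the design confounds with the genotype.

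The second pattern is that neighbouring genes share their direction, and that HLTF follows its neighbours. In the blocks with a median beyond 0.2 in size, 9.35% of the genes went against their block. A DNA copy number difference between the wild-type and knockout cells would give this, but so would any other shift shared by neighbours. Choosing blocks by their median also favours a low share in advance. Copy number is thus a candidate explanation that these counts cannot prove, as no DNA measurement was analysed here. The share was under the bound of 25% in 25 of the 26 blocks and at it in 1. That block, on chromosome 22 between 26443423 and 31134696 (10 of 40 genes), did not meet the bound, and the explanation stays open there as well. HLTF at percentile 52.5 of its neighbours argues against a loss of its transcript beyond theirs, though some of them lie outside the lowered stretch. Its log2 fold change of -0.48 was also smaller in size than the median of its block, -0.61. The 9 genes under 10% of their wild-type level in each knockout library argue against wild-type cells mixed into the knockout as the reason why HLTF mRNA remained. With its neighbour median removed SHPRH was still called, at 0.18 (adjusted p = 0.0117, within 3.05e-11 to 0.0117 over its alternatives), but percentile 85 among neighbours is short of the bound of 95 set for a rise of its own, so this and a shared shift cannot be told apart.

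The third pattern is that ZNF genes leaned higher. Outside chromosome 19 their median with neighbour medians removed was 0.063, beyond the bound of 0.05 set before the value was seen but by less than the standard error of the mean (0.0257), so a copy number difference and a rise of the family cannot be told apart there. In the last 2 blocks of chromosome 19 together, 35 of 48 ZNF genes and 7 of 32 other genes were called higher, and the medians differed by 0.18 (permutation test, p = 0.00101; p = 0.00079 from 52 Mb on and 2e-05 over the whole chromosome). Within a stretch, copy number as the whole cause would shift both alike. The values for the last 2 blocks and from 52 Mb on thus argue against it there, though genes are not independent replicates. The whole-chromosome value cannot do so, as it mixes stretches. From 52 Mb on lay 67 of the 170 ZNF genes compared but 46 of the 622 other genes. That the loss of SMARCA3 eases repression of ZNF clusters may be put as a hypothesis, untested here, since H3K9 methylation was not analysed.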
